A study of Mus musculus with 20 samples.

How the data were processed

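The data are 20 Affymetrix arrays of 45101 probe sets, from motor cortex and sensory cortex of 10 mice. Per the labels' protocols, EAE was induced in mice of 8 to 12 weeks with 100 µg of a myelin oligodendrocyte glycoprotein peptide in the flanks and 50 µg at the tail base, and 400 ng of pertussis toxin on days 0 and 3; healthy mice shared the cages, and no mock injection is described for them. The labels give day 21 for collection in the protocol and days 18 to 21 for the EAE mice elsewhere. Mice were perfused with saline and then a RNA-preserving solution, the forebrain was cut into 1 mm slices, and the regions were dissected with an atlas. Total RNA was labelled with biotin from 1 µg. The deposited values are on a log2 scale, from 3.79 to 15.1, and RMA and Partek are named in the submitters' processing notes, with versions not given in the sources used here. RMA corrects background, equalises the arrays' distributions and summarises the probes of a probe set, which compresses small differences at low signal. Array medians were not identical (8.22 to 8.32), and no raw scans were used here.

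Groups were taken from the labels: motor cortex of 6 EAE and 4 healthy mice and sensory cortex of the same mice. The labels' animal numbers show that the motor and sensory array of a number and condition come from the same animal, whereas EAE and healthy mice of a number are different animals. No 2 arrays held identical values, and the smallest root mean square difference within a group was 0.145. The correlation of the deviations from group means between the 2 arrays of a mouse was 0.163 to 0.587, except for EAE mouse 3 at -0.0316. Both cohorts hold both conditions. The arrays were processed on 2 days, and the second day holds 2 arrays, of motor cortex from healthy mouse 4 and sensory cortex from healthy mouse 1, so it could be tested only by leaving them out.

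Probe sets were named from the platform annotation supplied with the data: 34958 had 1 gene symbol, 932 had several and 9211 were not listed, and neither of the latter was named. Symbols were checked through Entrez identifiers against a RefSeq gene table of assembly GRCm38.p6, where 34754 probe sets matched and 0 symbols changed. No genome was used and no coordinates are given. For each of 18194 genes the probe set with the highest mean over all arrays was used. Of the genes called in motor and sensory cortex, 212 and 230 had several probe sets, all of the same sign for 164 and 168, and 3 and 1 had another probe set of opposite sign at an unadjusted p under 0.05. Of the genes named, S1pr3, Opalin, Serpinb1a and Slc38a3 in motor cortex and Ciita, Fcgr1, Etnppl, Igf2, Serpinb1a and Slc38a3 in sensory cortex had no other probe set changed in the same direction at that level, and Ighm in motor cortex had 2 of 10.

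Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) with cohort as a covariate, and genes were called at a Benjamini-Hochberg adjusted p under 0.05; each printed adjusted p for a gene is from limma. Motor and sensory cortex were fitted separately, with 10 arrays each. For both regions together each mouse's 2 arrays were averaged, and for the difference between the regions each mouse's motor minus sensory value was fitted. Motor was compared with sensory cortex with the mouse as a block. Changes are log2 EAE minus healthy with the moderated SE and 95% intervals. Lists of genes were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry. Fry asks whether a list's genes move one way on balance and does not compare them with other genes. Of 340 entries in 30 lists, 308 were measured; the others, such as C4b, C3 and Isg15, had no probe set with that single symbol and were not used here. Camera and the list counts were run per region as planned, and those for the difference between regions, the combined arrays and motor against sensory were added. Exact permutation tests of list means used all 210 splits of the 10 mice.

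The design, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule took, for each region, the 10 largest rises and 10 largest falls among called genes, up to 4 members with the smallest p of each list, and a fixed set (Gfap, Lcn2, Serpina3n, C4b, Cd74, H2-D1, B2m, Cx3cr1, Mbp, Slc17a7, Gad1, Pvalb, Fos, Arc and Fkbp5; a further gene is not reported here). For the other comparisons it took the 10 smallest adjusted p in each direction, or the 5 smallest p where none passed. Other list members that are named were chosen after their values were seen. Of the fixed set, Gad1 stood at 0.15 ± 0.09 in motor and 0.20 ± 0.08 in sensory cortex (SE, log2), not past the threshold.

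The fits were tested on simulated data with 200 of 18194 genes changed. At a log2 change of 1 the share recovered was 99% in motor cortex, 99% in sensory cortex, 99% for both together, 98% for the difference between regions and 100% for motor against sensory; at 0.5 it was 88%, 84%, 92%, 69% and 99%. With no change simulated 0 genes were called. The simulated spread was independent between genes and equal in the groups compared, which does not hold for the real arrays. In motor cortex the interferon list's mean had an SD of 0.648 in EAE and 0.0509 in healthy mice. The shares recovered therefore need not hold for genes that vary between EAE mice. Alternatives were the mean of a gene's probe sets, every probe set, a filter on the dimmest 33.3% of genes, 2 further normalizations, eBayes with trend and robust, array weights, no cohort term, each cohort alone, the second array day left out, the mouse number as a block, 1 fit over all arrays and each mouse left out. Covariates for array median and RNA quality, EAE mice alone for the regions, grade with cohort means taken off, and the overlap of the regions' genes in regrouped residuals were added after the data were seen. RNA quality was the difference between the beta-actin 3' and 5' control probe sets, from 0.345 to 0.832. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.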

Results

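Experimental autoimmune encephalomyelitis (EAE) is a mouse model of multiple sclerosis in which an immune response against a myelin peptide causes ascending paralysis. Gene expression was measured with Affymetrix arrays in tissue enriched for motor cortex and for sensory cortex, taken from the same 10 female C57Bl6 mice. There were 6 mice with EAE, with average grades from 2.5 to 3.5, and 4 healthy mice from the same cages, which gave 20 arrays, 1 per region and mouse. The mice came from 2 cohorts, each with 3 EAE and 2 healthy mice. The labels describe the peptide and pertussis toxin injections for the EAE mice alone, so each comparison holds the immunisation as well as the disease. Values are log2 expression as deposited. Array medians lay between 8.22 and 8.32, arrays of a group correlated at 0.988 to 0.998 across probe sets, and the number of arrays limits the precision.

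The first comparison asked which genes differed between EAE and healthy mice in motor cortex. The largest rise was that of Lcn2, the secreted iron-siderophore carrier lipocalin 2, from 5.36 ± 0.10 (SD, n = 4) to 8.03 ± 1.11 (SD, n = 6), a 6.35-fold difference with a limma adjusted p of 0.00314. The healthy values lie far below the array medians and no detection calls were used here. Background may therefore compress this fold and that in sensory cortex, which was not tested, and both are read as approximate. S100a8 and S100a9, the subunits of the calcium-binding protein calprotectin, rose by 1.89 ± 0.14 and 1.37 ± 0.17 on the log2 scale (SE). Plin4, a lipid droplet coat protein, rose by 1.83 ± 0.18, Etnppl, an astrocyte enzyme that degrades phosphoethanolamine, by 1.56 ± 0.12, the sulfotransferase gene Sult1a1 by 1.42 ± 0.15, and Lrg1, a secreted glycoprotein of activated endothelium, by 1.41 ± 0.10. The largest falls were those of Abi3bp, an extracellular matrix protein, which fell by 1.50 ± 0.08, of the microglial receptor Gpr34, which fell by 1.19 ± 0.12, of the brain fatty acid binding protein Fabp7, which fell by 1.11 ± 0.11, and of Serpinb1a, a protease inhibitor, which fell by 1.08 ± 0.16. Over 18194 genes, limma with Benjamini-Hochberg adjustment called 410, of which 94 rose and 316 fell. Of these, 12 were at least 2-fold higher and 5 at least 2-fold lower.

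Among microglial genes in motor cortex, 4 of the 11 measured members of the homeostatic list fell, and 10 fell when adjusted over the list alone. P2ry12, the purine receptor that marks resting microglia, fell by 0.97 ± 0.11, P2ry13 fell by 0.57 ± 0.09 and Siglech fell by 0.40 ± 0.08 (SE, log2). Cx3cr1, the fractalkine receptor, stood at -0.56 ± 0.14 with an adjusted p of 0.0623. The list's median was -0.40, and limma's camera gave it an adjusted p of 6.11e-11, or adjusted p = 0.0175 with an estimated correlation. Of the 17 measured genes of activated microglia and macrophages, Itgax rose by 0.35 ± 0.08 and Lpl, a lipoprotein lipase, fell by 0.62 ± 0.10. The list's median was 0.27, with a camera adjusted p of 0.00663 that became 0.0614 without healthy mouse 3 (adjusted p = 0.42 with an estimated correlation).

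In motor cortex the neutrophil and monocyte list and the endothelial activation list were called upward. In the neutrophil and monocyte list 3 of 12 measured members rose, namely S100a8, S100a9 and the granule protein gene Ngp at 0.48 ± 0.07, and 8 rose when adjusted over the list alone. Camera gave that list an adjusted p of 7.68e-11 and adjusted p = 0.0175 with an estimated correlation. In the list of endothelial activation and acute phase, Lrg1, Vwf (von Willebrand factor, 0.69 ± 0.13) and the interleukin-1 receptor gene Il1r1 (0.39 ± 0.06) rose among 11 measured members, and 5 rose and 1 fell when adjusted over the list alone. Its camera adjusted p was 1.25e-06, and adjusted p = 0.0461 with an estimated correlation. Endothelial identity genes went both ways: Slco1c1, the thyroid hormone transporter of the blood-brain barrier, fell by 0.54 ± 0.05, and the receptor tyrosine kinases Tie1 and Tek fell by 0.46 ± 0.09 and fell by 0.40 ± 0.07, whereas the lysolipid transporter Mfsd2a rose by 0.39 ± 0.08. With 1 of 14 members up and 3 down (2 and 6 when adjusted over the list alone), this list had a median of -0.12, which was -0.18 without EAE mouse 4 or healthy mouse 3, and a camera adjusted p of 0.00477, and adjusted p = 0.253 with an estimated correlation.

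Antigen presentation and interferon genes had high but uneven values in the motor cortex of EAE mice. H2-K1 and H2-D1, the classical major histocompatibility complex (MHC) class I chains, rose by 0.91 ± 0.21 and 0.79 ± 0.16. No member of the class II list (6 measured) or the interferon list (22 measured) passed the test over all genes, although Cd74, the class II invariant chain, stood at 1.71 ± 0.45 (adjusted p 0.0715) and H2-Aa at 2.02 ± 0.58 (adjusted p 0.104). The 3 other probe sets of H2-Aa stood at 1.19, 1.23 and 0.36. When adjusted over the list alone, 7 of 11 class I, 4 class II and 13 interferon genes rose. The medians were 0.72, 1.04 and 0.68, with camera adjusted p of 2.69e-07, 0.000199 and 1.86e-11. All 3 calls were lost at adjusted p = 0.253 with an estimated correlation. The interferon list's mean lay above every healthy mouse in 5 of the 6 EAE mice and below them in EAE mouse 1. The exact two-sided permutation p of its mean difference was 0.0619 before adjustment over the lists and 0.124 after. For the class I and class II lists the adjusted permutation p were 0.0879 and 0.0714.

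Glucocorticoid responsive genes were higher in motor cortex. Fkbp5, a chaperone that the glucocorticoid receptor induces, rose by 1.04 ± 0.14 (SE, log2), and with Plin4 and Sult1a1 it made 3 of 13 members that rose, or 7 when adjusted over the list alone. The list's camera adjusted p was 7.22e-09, and adjusted p = 0.143 with an estimated correlation. In the reactive astrocyte list Lcn2 and the ferroxidase gene Cp (0.49 ± 0.08) rose and the sphingosine phosphate receptor gene S1pr3 fell by 0.32 ± 0.07. The 2 other probe sets of S1pr3 stood at -0.16 and 0.14, neither at an unadjusted p under 0.05. The list had 12 measured members, of which 6 rose and 1 fell when adjusted over the list alone (camera adjusted p 0.000519, and adjusted p = 0.177 with an estimated correlation). Gfap, the astrocyte intermediate filament, stood at 0.65 ± 0.23 with an adjusted p of 0.176. Of 12 astrocyte identity genes, the connexin gene Gjb6 rose by 0.58 ± 0.08, and the list was not called (adjusted p 0.832).

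Mature oligodendrocyte genes were lower in motor cortex. The galactolipid enzyme gene Ugt8a fell by 0.69 ± 0.07, Opalin fell by 0.62 ± 0.14, the myelin-associated glycoprotein gene Mag fell by 0.45 ± 0.09 and Aspa fell by 0.44 ± 0.09, 4 of 13 measured members, with 9 lower when adjusted over the list alone. Mbp, myelin basic protein, stood at -0.04 ± 0.07 with an adjusted p of 0.81 on its brightest probe set, which lies near the top of the arrays' range (14.4). Of its 7 other probe sets 4 were lower at an unadjusted p under 0.05, by -0.27 to -0.14, and in sensory cortex 1 was, at -0.25. The list's median of -0.35 became -0.21 without healthy mouse 2, whose Mbp and Aspa values were the highest of its group. Its camera adjusted p was 3.75e-07, and adjusted p = 0.253 with an estimated correlation. In the cholesterol synthesis list Hmgcs1 fell by 0.27 ± 0.06 among 13 members, and 8 fell when adjusted over the list alone (camera adjusted p 1.39e-05, and adjusted p = 0.223 with an estimated correlation).

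Neuronal lists were not called by camera in motor cortex, although single members went both ways. The lists of excitatory neurons, inhibitory neurons, synapses, immediate early genes and oxidative phosphorylation had medians between -0.02 and 0.05 and camera adjusted p from 0.368 to 0.932. Slc17a7, the cortical vesicular glutamate transporter, stood at 0.01 ± 0.09 (95% interval -0.19 to 0.20), and the parvalbumin gene Pvalb at 0.03 ± 0.08. Fos stood at 0.35 ± 0.26 and Arc at -0.16 ± 0.22. The neuropeptide gene Vip rose by 0.31 ± 0.06. The somatostatin gene Sst stood at -0.26 ± 0.06 (adjusted p 0.0567) and the serotonin receptor gene Htr3a at 0.25 ± 0.07 (adjusted p 0.0842). The immediate early gene Fosb stood at 1.03 ± 0.39 (adjusted p 0.218). Of 12 inhibitory neuron genes 2 rose and 1 fell when adjusted over the list alone, with a fry p for change in either direction of 5.91e-06. In the 4 other lists 0 did. Among lists of other cells, the B and plasma cell list had a median of -0.01, a mean of -0.11 and a test direction upward, with an adjusted p of 0.968, although its member Ighm fell by 1.01 ± 0.19. The excitatory neuron list had a median of 0.01 and a mean of -0.04. The T cell list, in which the chemokine gene Ccl5 rose by 0.53 ± 0.12, the complement list, the mural list and the striatum list had camera adjusted p of 0.0379, 3.77e-06, 0.0415 and 0.0415, with adjusted p = 0.253, adjusted p = 0.169, adjusted p = 0.289 and adjusted p = 0.375 with an estimated correlation. The first was lost without any of EAE mice 1, 2 and 4 or healthy mouse 2, at 0.0888, 0.0795, 0.0698 and 0.0516. The mural list was lost without EAE mice 1, 4 and 6 or healthy mice 2 and 4, at 0.0888, 0.069, 0.069, 0.184 and 0.111, and the striatum list without EAE mice 3 and 6 or healthy mice 2 and 3, at 0.169, 0.0739, 0.409 and 0.0801. The immediate early list was called without EAE mouse 2, at 0.0192, or healthy mouse 1, at 0.00963. The lists of oligodendrocyte precursors, cortical layers, choroid plexus, meninges and blood had adjusted p from 0.0983 to 0.972, and the upper layer list had a median of -0.02 and a test direction upward. Of 8 meninges genes Igfbp2 fell by 0.75.

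The motor cortex count depended on single mice and cohorts. It was 145, 180, 194 and 194 without healthy mice 1, 2, 3 and 4, 269 without EAE mouse 2, 236 without EAE mouse 5, and 9 and 16 within cohorts 1 and 2, and quantile normalization of the arrays gave 120 rises against 227 falls. Without the motor array of the second processing day, that of healthy mouse 4, it was 194 likewise. Of 80 genes examined singly 50 were called, and 29 of these, among them Lcn2, S100a8, Plin4, Abi3bp, Gpr34 and P2ry12, were called whichever mouse was left out, while 21 lost the call without at least 1 mouse.

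**Figure D1:**
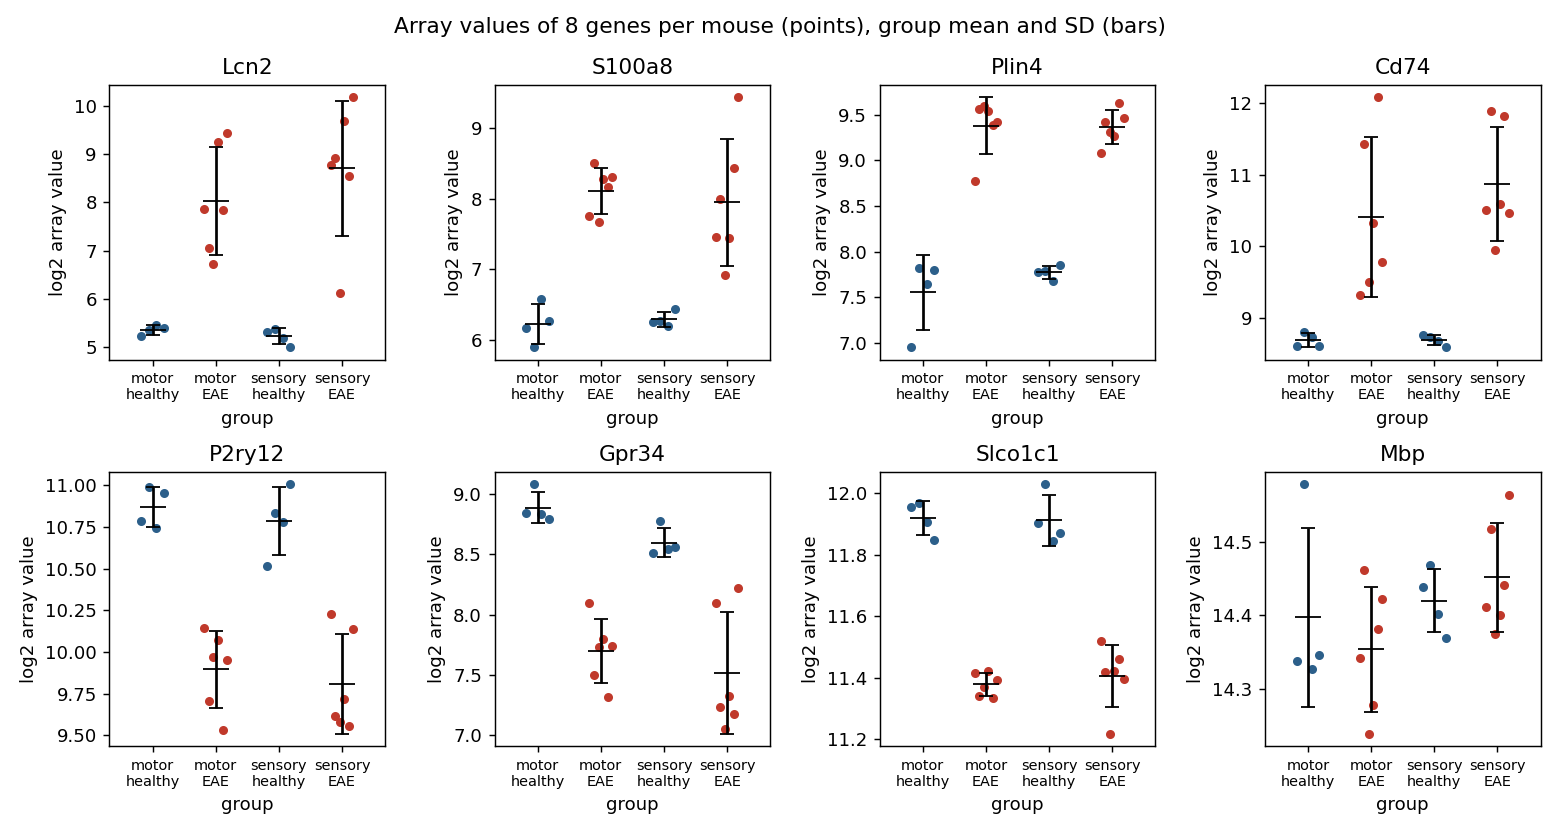
Log2 array values of 8 genes in the 4 groups, with a point per mouse (6 EAE in red, 4 healthy in blue) and bars for the mean ± SD. The EAE values of Lcn2, S100a8 and Plin4 lie above and those of P2ry12, Gpr34 and Slco1c1 below all healthy values of the same region, while the Mbp values overlap.

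The second comparison made the same contrast in sensory cortex. Lcn2 again had the largest rise, from 5.22 ± 0.17 (SD, n = 4) to 8.70 ± 1.41 (SD, n = 6), an 11.2-fold difference with a limma adjusted p of 0.0214. MHC class II genes were among the next: H2-Aa rose by 2.83 ± 0.47, Cd74 by 2.17 ± 0.36 and H2-Eb1 by 1.51 ± 0.29 on the log2 scale (SE). The 3 other probe sets of H2-Aa showed smaller rises, of 1.46, 1.53 and 0.44. The monocyte-attracting chemokine gene Ccl12 rose by 2.11 ± 0.36, S100a8 by 1.66 ± 0.36, Plin4 by 1.59 ± 0.09, Sult1a1 by 1.53 ± 0.13, Etnppl by 1.51 ± 0.11 and Lrg1 by 1.51 ± 0.08. Abi3bp fell by 1.56 ± 0.29, Serpinb1a fell by 1.15 ± 0.23, Gpr34 fell by 1.08 ± 0.23, the troponin gene Tnnc1 fell by 1.02 ± 0.20, Fabp7 fell by 0.99 ± 0.13 and P2ry12 fell by 0.98 ± 0.15. Of the 18194 genes limma called 438, of which 164 rose and 274 fell, 23 at least 2-fold higher and 4 at least 2-fold lower.

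In sensory cortex the lists of antigen presentation, interferon response, complement, activated microglia, neutrophils and monocytes, and T cells were called upward, and the B and plasma cell list was not called. In the class II list Cd74, H2-Aa, H2-Eb1 and the transactivator gene Ciita (0.28 ± 0.05) rose among 6 measured members, 5 when adjusted over the list alone. The 2 other probe sets of Ciita stood at 0.08 and 0.02, neither at an unadjusted p under 0.05. In the interferon list Ifi27l2a (1.45 ± 0.24), Ifit3 (1.18 ± 0.25) and Ifit1 (1.05 ± 0.23) rose among 22, and 21 rose when adjusted over the list alone. In the class I list H2-K1 (1.05 ± 0.18), H2-D1 (0.79 ± 0.13) and B2m (0.38 ± 0.08) rose among 11, and 10 when adjusted over the list alone. The medians of these lists were 1.57, 1.08 and 0.79, with camera adjusted p of 4.24e-07, 8.78e-15 and 2.95e-08, and with adjusted p = 0.272, adjusted p = 0.277 and adjusted p = 0.288 with an estimated correlation. Complement component gene C1qb rose by 0.60 ± 0.14 among 9 complement genes, 6 of which rose when adjusted over the list alone (camera adjusted p 2.06e-06, and adjusted p = 0.272 with an estimated correlation). Among 17 genes of activated microglia and macrophages Cd52 (1.34 ± 0.28), the Fc receptor gene Fcgr1 (0.78 ± 0.17), the protease gene Ctss (0.64 ± 0.10) and Itgax (0.38 ± 0.08) rose, and 8 rose and 1 fell when adjusted over the list alone (camera adjusted p 1.47e-05, and adjusted p = 0.314 with an estimated correlation). In the neutrophil and monocyte list S100a8 rose among 12 members, 8 when adjusted over the list alone (camera adjusted p 2.7e-06, and adjusted p = 0.272 with an estimated correlation). The T cell list, with no member called and 1 higher when adjusted over the list alone, had a camera adjusted p of 0.0156, and adjusted p = 0.326 with an estimated correlation. Adjusted exact permutation p were 0.0357 for complement, 0.0429 for activated microglia, and 0.0286 for each of the neutrophil and T cell lists. For the B and plasma cell list it was 0.221.

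Glial and vascular lists in sensory cortex had the directions seen in motor cortex. P2ry12, Gpr34 and P2ry13, which fell by 0.61 ± 0.13, were the 3 of 11 homeostatic microglia genes that fell, with 7 lower when adjusted over the list alone (median -0.32, camera adjusted p 2.36e-05, and adjusted p = 0.272 with an estimated correlation). Of 12 reactive astrocyte genes Lcn2, Cp (0.68 ± 0.13) and the serpin gene Serpina3n (0.57 ± 0.13) rose, 5 when adjusted over the list alone (median 0.25, or 0.17 without EAE mouse 2, camera adjusted p 1.47e-05, and adjusted p = 0.277 with an estimated correlation), and Gfap stood at 0.97 ± 0.24 with an adjusted p of 0.0645. Lrg1, Vwf (0.88 ± 0.10), Ch25h (0.84 ± 0.19) and the adhesion molecule gene Icam1 (0.65 ± 0.12) rose among 11 genes of endothelial activation, 6 when adjusted over the list alone (camera adjusted p 2.16e-07, and adjusted p = 0.0818 with an estimated correlation). Tie1, Slco1c1, Kdr and Tek fell by 0.61 ± 0.10, fell by 0.51 ± 0.07, fell by 0.48 ± 0.10 and fell by 0.39 ± 0.07, while Mfsd2a rose by 0.52 ± 0.06 and the glucose transporter gene Slc2a1 by 0.48 ± 0.11. The endothelial identity list's camera adjusted p of 0.0218 (adjusted p = 0.411 with an estimated correlation) was 0.206 without healthy mouse 2 and 0.0669 without EAE mouse 1, and its median of -0.15 was -0.10 without EAE mouse 3. Fkbp5 rose by 1.13 ± 0.15, and with Plin4 and Sult1a1 made 3 of 13 glucocorticoid responsive genes that rose, 9 when adjusted over the list alone (camera adjusted p 2.08e-08, and adjusted p = 0.0979 with an estimated correlation). Mag fell by 0.45 ± 0.10 among 13 oligodendrocyte genes, with 8 lower when adjusted over the list alone (camera adjusted p 0.000759, and adjusted p = 0.475 with an estimated correlation), and Dhcr7 fell by 0.39 ± 0.09 among 13 cholesterol synthesis genes, with 6 lower and 1 higher when adjusted over the list alone (camera adjusted p 0.00314, and adjusted p = 0.468 with an estimated correlation). Among the neuronal lists the medians lay between -0.12 and 0.04 with adjusted p from 0.368 to 0.796, and Vip rose by 0.41 ± 0.06. When adjusted over the list alone, 1 inhibitory neuron gene rose and 1 fell, and 1 synapse gene fell. The unadjusted fry p for change in either direction was 0.000128 for inhibitory neurons, 0.0003 for synapses and 0.0187 for excitatory neurons. The choroid plexus list, with no member called, had a median of 0.11 and a camera adjusted p of 0.0314 (adjusted p = 0.314 with an estimated correlation), which became 0.0796, 0.0584 and 0.0571 without EAE mouse 2, EAE mouse 4 and healthy mouse 1. The other lists were not called, with adjusted p from 0.102 to 0.927, although the astrocyte identity list was at 0.0475 without EAE mouse 3 and 0.0199 without healthy mouse 2, the meninges list at 0.0216 without healthy mouse 2 and the striatum list at 0.0228 without healthy mouse 3. Of 8 meninges genes Igf2 rose by 0.60, with its other probe set at 0.14. The B and plasma cell list and the oligodendrocyte precursor list had medians of 0.01 and 0.03 with means of -0.09 and -0.03 and a test direction downward.

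The number of genes called in sensory cortex depended on single mice, cohorts and settings. It was 118, 48, 30 and 19 without healthy mice 1, 2, 3 and 4, and 1009, 182, 186, 105 and 252 without EAE mice 1, 2, 4, 5 and 6. It was 0 within cohort 1 by limma, with 871 genes at an unadjusted p under 0.05, 141 within cohort 2, 6 with the array median and an RNA quality measure as covariates, and 193 rises against 182 falls after quantile normalization of the arrays. Of 58 called genes among the 80 examined singly, 9 were called whichever mouse was left out, among them Plin4, Etnppl, Sult1a1, Lrg1, Vwf and Mfsd2a, and 49 lost the call without at least 1 mouse.

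**Figure D2:**
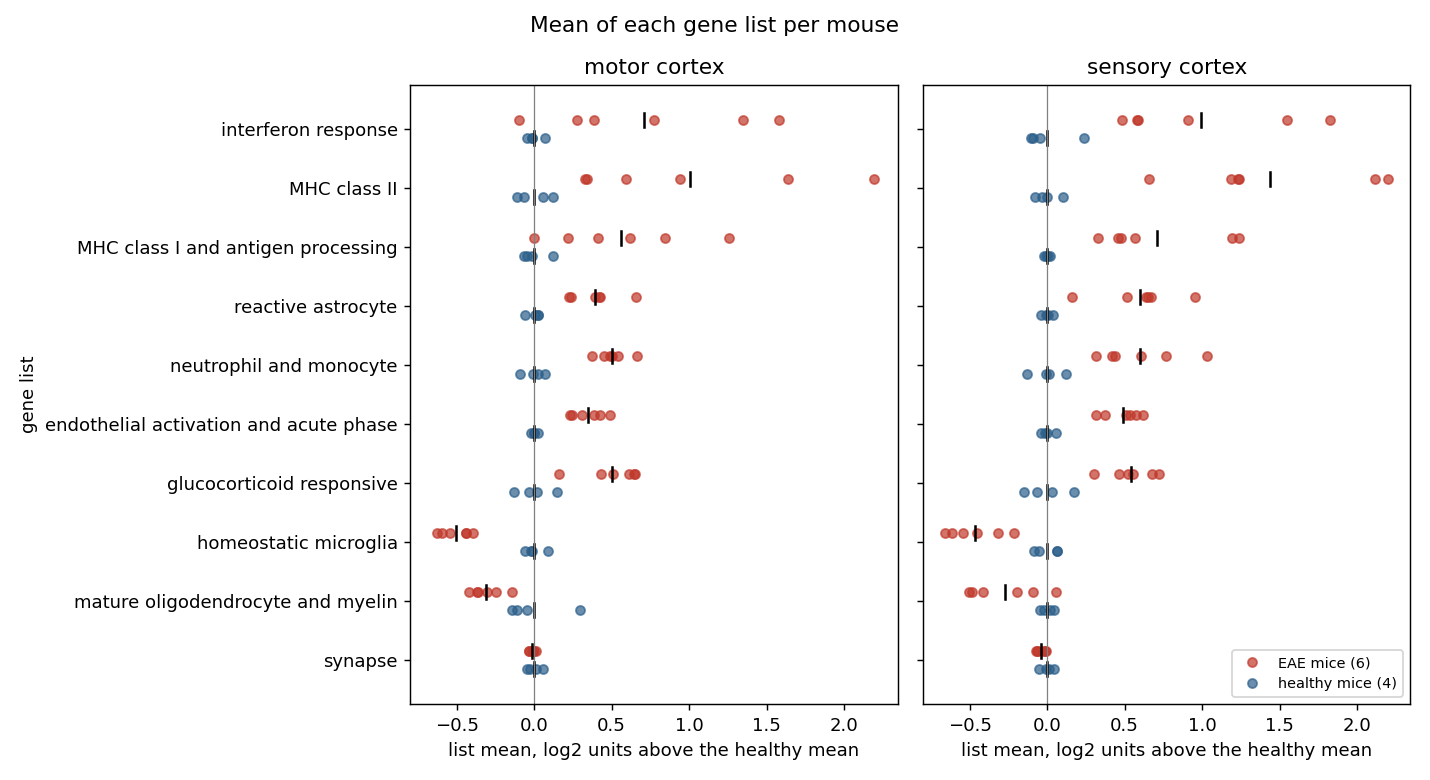
Mean of each of 10 gene lists per mouse (points, 6 EAE in red and 4 healthy in blue), in log2 units above the healthy mean of the same region, with a black bar at each group mean. In motor cortex the homeostatic microglia mean is -0.51 and the glucocorticoid mean 0.50 in EAE mice, and the EAE values of the interferon list spread from -0.10 to 1.58.

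The 2 regions were then combined, with each mouse's arrays averaged. The smallest adjusted p among rises were those of Lrg1 at 1.46 ± 0.08 (SE, log2, adjusted p 2.53e-05), Plin4 at 1.71 ± 0.11 and Etnppl at 1.54 ± 0.11, and among falls those of Slco1c1, which fell by 0.52 ± 0.04 (adjusted p 0.000626), and of the endothelial sialomucin gene Emcn, which fell by 0.68 ± 0.07. Cd74, at 1.94 ± 0.41, passed the threshold here with an adjusted p of 0.0184, and Cx3cr1 fell by 0.64 ± 0.17 with an adjusted p of 0.0468. Limma called 1431 genes, 405 higher and 1026 lower, and quantile normalization of the arrays gave 450 higher and 603 lower. The count was 766, 691, 563 and 472 without healthy mice 1, 2, 3 and 4, 779 without EAE mouse 5, 574 within cohort 2 and 0 within cohort 1, with 1813 genes there at an unadjusted p under 0.05. It was 6 without the 2 healthy mice that have an array of the second processing day.

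The log2 changes of motor and sensory cortex were then compared. Across genes, which are not independent replicates, the log2 changes correlated at 0.833 with a covariance of 0.0211. Both regions come from the same mice, and regrouped mice with the EAE effect removed gave correlations from -0.114 to 0.64 (median 0.221) and a median covariance of 0.0015 in 99 regroupings. Between mice of different cohorts, where no mouse is shared, the correlation was 0.553 for motor cortex of cohort 1 with sensory cortex of cohort 2 and 0.557 for the reverse, with covariances of 0.0198 and 0.017. The regions shared 56 called rises and 114 called falls, against 0.847 and 4.76 for independent lists of these sizes. With the EAE effect removed and the mice regrouped, as many genes per region, taken by smallest p, shared a median of 9 higher (0 to 86) and 9 lower (0 to 107). The shared rises lay within that range and the shared falls above it. Of the 678 genes called in either region 672, or 99.1%, had the same sign in both, against 65.6% in the median regrouping (38.6 to 93.5%).

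**Figure D3:**
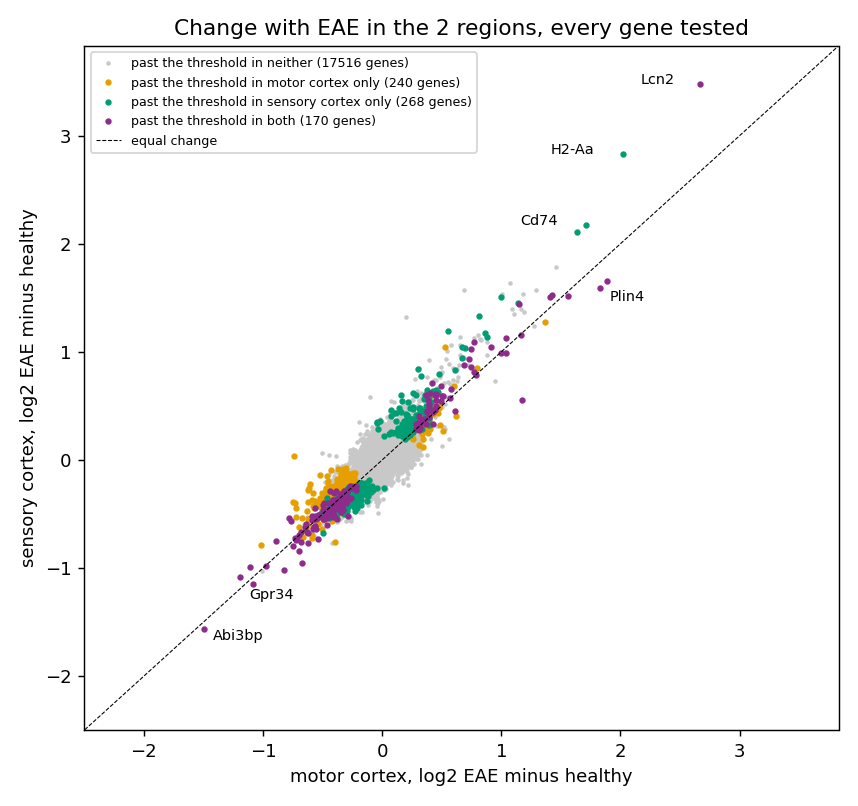
Log2 change with EAE in motor cortex (horizontal axis) and sensory cortex (vertical axis) for each of the 18194 genes tested, coloured by where the gene passed the adjusted p threshold; the dashed line marks equal change. Among the 170 genes past the threshold in both regions, Lcn2 lies above the line (2.67 in motor and 3.48 in sensory cortex) and Spink8 below it (1.17 and 0.55).

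Whether the EAE effect differed between the regions was tested on each mouse's motor minus sensory value. The smallest p in favour of motor cortex was that of Spink8, whose effect was larger there by 0.62 ± 0.13 (SE, log2), and those in favour of sensory cortex were H2-Ab1, at -0.56 ± 0.11, Pappa2, at -0.78 ± 0.16, and the chemokine gene Cxcl10, at -0.89 ± 0.19. None of these passed: limma called 0 of the 18194 genes, with 422 at an unadjusted p under 0.05, and the smallest adjusted p was 1. For Lcn2 the difference was -0.81 ± 0.35. The mean of the class II list differed by -0.43, with the larger effect in sensory cortex in 5 of 6 EAE mice (exact two-sided permutation p 0.0381, adjusted p 0.229 over 30 lists), and that of the endothelial activation list by -0.14 in 6 of 6 mice (exact permutation p 0.0143, adjusted p 0.214). The smallest exact permutation p was that of the mural list, at 0.00952. The mean of that list was lower by more in motor cortex (-0.11) than in sensory cortex (-0.03), in 6 of 6 mice. The astrocyte identity and complement lists had exact p of 0.0238 and 0.0286 with differences of -0.07 and -0.16, each in 6 of 6 mice and with an adjusted p of 0.214. No list passed that adjustment. Camera with its preset correlation called 12 lists for this difference, among them the interferon list at an adjusted p of 6.46e-17, and called 0 with an estimated correlation (adjusted p = 0.152 for the interferon list), as fry did.

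Motor and sensory cortex were compared within mice to see how the dissections differed. The 6 EAE and 4 healthy mice were pooled, so any regional difference in the EAE effect enters this comparison too. Markers of layer 4, the input layer that is thick in sensory cortex, were lower in motor cortex: Rspo1 fell by 1.20 ± 0.10 and Rorb fell by 1.17 ± 0.05 from sensory to motor (SE, log2, n = 10 mice), and all 4 list members passed. Upper layer genes were lower too, with all 5 measured members called and Cux1 at -0.66 ± 0.04. Of 7 deep layer genes 4 were higher in motor cortex, with Crym at 1.59 ± 0.13, a 3.0-fold difference, and Fezf2, a selector of subcortical projection neurons, at 0.72 ± 0.06. The largest of the other named differences were Cyp39a1 at -2.05 ± 0.11, the peptide gene Cartpt at -1.61 ± 0.08 and the thalamic-type glutamate transporter gene Slc17a6 at -1.27 ± 0.06. Mural genes were lower in motor cortex, 5 of 9, including Acta2 at -0.23 ± 0.04, and the striatal list's Tac1 was higher at 0.88 ± 0.07. The striatal list as a whole was not called, with 2 of 6 members higher, a median of 0.06 and a camera adjusted p of 0.178. Limma with the mouse as a block called 2408 genes, 1396 higher and 1012 lower in motor cortex. Camera called 15 lists, and the layer 4, upper layer and mural lists kept their call at adjusted p = 0.0202 with an estimated correlation, while the deep layer list (camera adjusted p 0.00029) was lost at adjusted p = 0.218 with an estimated correlation. Lists higher with EAE were among those called: 8 of 22 interferon and 4 of 11 class I genes were lower in motor cortex. Their camera adjusted p were 6.34e-09 and 0.000212, lost at adjusted p = 0.365 and adjusted p = 0.421 with an estimated correlation.

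**Figure D4:**
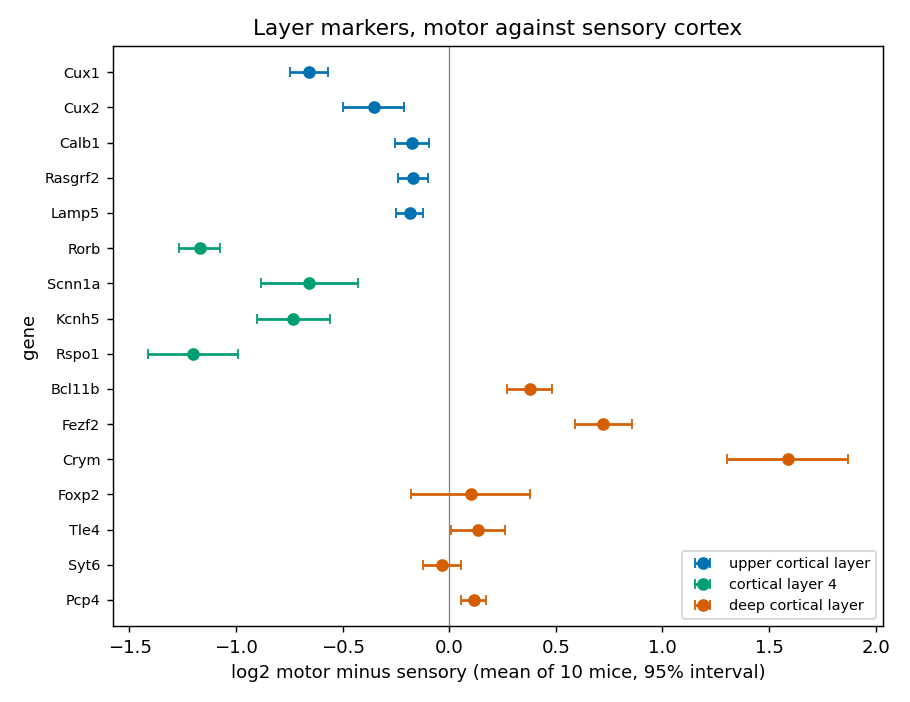
Log2 difference between motor and sensory cortex for measured markers of upper layers, layer 4 and deep layers (points, mean of 10 mice, with 95% intervals from limma). The layer 4 markers lie between Rspo1 at -1.20 and Scnn1a at -0.66, and Crym is highest at 1.59.

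The labels give an average clinical grade for each EAE mouse, and the list means over both regions were set against it. The endothelial activation list had the highest positive correlation (Pearson r 0.849, exact permutation p 0.0389; Spearman rho 0.912, exact p 0.0222), the glucocorticoid list had r 0.819 (exact p 0.0444) and rho 0.794 (exact p 0.0667), and the oligodendrocyte precursor list had r -0.866 (exact p 0.0167) and rho -0.971 (exact p 0.0111), the largest in size. The neutrophil and monocyte list had r 0.734 (exact permutation p 0.106, adjusted p 0.528) and rho 0.853 (exact p 0.0444). Over 30 lists none of these passed Benjamini-Hochberg adjustment, with adjusted p of 0.444 for Pearson in the first 3 and 0.333 to 0.4 for Spearman, from 6 mice. EAE mice 1, 5 and 6 were equally far from the median grade, and a second fit left out mice 1 and 5. That choice among tied mice was arbitrary, and the other choices were not run. Without mice 1 and 5, r was 0.921 for the endothelial activation and 0.446 for the glucocorticoid list. It was -0.849 for the precursor and 0.787 for the neutrophil and monocyte list. Grade overlaps cohort, since the mice of cohort 1 had 2.5, 3 and 2.75 and those of cohort 2 had 3, 3.5 and 3.5. With the cohort means taken off, a test added after the results were seen, r was 0.509 for the endothelial activation list (exact permutation p 0.389), 0.739 for the glucocorticoid list (exact p 0.167), -0.836 for the oligodendrocyte precursor list (exact p 0.111) and 0.828 for the neutrophil and monocyte list (exact p 0.167), each with an adjusted p of 0.729. The 18 orders of the grades within cohorts can give no p below 0.0556.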

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

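The tests of the spread of the interferon list between mice were chosen after its values per mouse were seen; those of the other 2 patterns were written down after the genes' results and before the tests were run.

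Glucocorticoid responsive genes were higher in the EAE cortex of both regions by camera with its preset correlation, a call lost with an estimated one (adjusted p = 0.143 in motor, 0.0979 in sensory cortex and 0.157 over both). Without the sensory array of EAE mouse 3, which had the lowest mean correlation with its group (0.989), the list's median change in sensory cortex kept 0.874 of its size (0.27 against 0.31). With array median and RNA quality as covariates the median over both regions kept 0.87 of its size (0.29 against 0.33). These values argue against that array as the whole source in sensory cortex, and against quality or brightness as such over both regions. The list was not refitted with the covariates in sensory cortex alone, where they cut the genes called from 438 to 6. A second list of 12 genes known to respond to glucocorticoids, 11 of them measured, had a median of 0.28 over both regions, with 5 higher and 0 lower, among them Cebpd at 0.82 ± 0.15 and Rhou at 0.35 ± 0.08 (SE, log2), and a camera p of 2.42e-07, or an unadjusted p of 0.0385 with an estimated correlation. A raised glucocorticoid signal in sick mice is therefore a candidate explanation, a hypothesis that these data cannot separate from handling, from the injections or from inflammation, which also raises genes such as Cebpd.

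Homeostatic microglia genes were lower in EAE cortex, with a mean log2 change of -0.49 over both regions (exact permutation p 0.00476, the smallest that 210 splits can give; camera adjusted p = 0.0175 in motor, 0.272 in sensory cortex and 0.108 over both with an estimated correlation). A broad set of 15 other microglial genes had a mean change of 0.20 (exact permutation p 0.133). The difference between the sets had an exact permutation p of 0.00952. This argues against a lower microglial share as sole source only if no other cells brought these genes and microglia did not raise them. Ctss, Cd68, Tyrobp and Trem2 of the broad set are also in the activated microglia list, so the test cannot settle it. Within that broad set Ctss and C1qb rose by 0.55 ± 0.10 and 0.48 ± 0.13 over both regions (SE). Itgam and Trem2 fell by 0.41 ± 0.10 and 0.22 ± 0.06. Without EAE mouse 3 the fall kept 0.953 of its size (exact permutation p 0.00794). As a hypothesis only, resident microglia may have left the resting state, which no test here measures apart from cell composition. Cells entering from the blood that carry the broad genes, or a rise of these genes within microglia, could mask a loss of microglia.

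The interferon response list means spread widely between EAE mice, from 0.24 to 1.59 log2 units above healthy over both regions. The motor and sensory values of the 6 EAE mice correlated at r 0.914 (exact permutation p 0.0153; Spearman rho 0.771, exact p 0.103; r 0.695 without the 2 mice farthest from the median; adjusted p 0.111 over 30 lists), which argues against noise of single arrays. The cohorts' EAE mice overlapped, with a difference of 0.193 between their means. The relation to clinical grade had r 0.467 (exact permutation p 0.339, adjusted p 0.676) and rho 0.618 (exact p 0.222). Without EAE mice 1 and 5, which tied with mouse 6 as farthest from the median grade, r was -0.190. With cohort means taken off, r was 0.549 (exact permutation p 0.278). A relation to grade cannot be told apart from none with 6 mice. A mouse-wide difference in interferon signalling may thus remain, as a hypothesis, with the day of disease and the grade among the open sources.

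Other splits of the 10 mice into groups of 6 and 4 were used to ask whether the gene counts could come from any grouping. In motor cortex 1 of 100 splits (the real one, 410 genes) called as many, with 301 as the highest of the others; in sensory cortex 1 of 100 (438 against 205); for both regions 1 of 100 (1431 against 130). Swapping the regions within mice gave 1 of 100 with as many as 2408 genes, against 1410. Each of these counts was thus the highest of the 100 groupings drawn. For the splits of the mice, the real grouping is 1 of the 100, so no probability below 1 in 100 can be shown. For the swaps the number of mice swapped was drawn first. Patterns close to the real labels were thus drawn more often than evenly, and no probability can be read from the swaps. For the difference between the regions 0 genes were called, so every split necessarily gave at least as many and the splits decide nothing. The highest other count there was 1. The motor split with 301 genes set EAE mice 2, 5 and 6 and healthy mouse 2 apart, the 4 motor arrays with the lowest medians (8.22 to 8.24, against 8.28 to 8.31). The sensory split with 205 genes set EAE mice 1 and 2 and healthy mice 2 and 4 apart, which include the 2 brightest sensory arrays (8.30 to 8.32) and 2 of the 3 dimmest (8.23 to 8.24), and neither split was rerun with brightness accounted for. With the median and RNA quality as covariates the real comparisons called 375 genes in motor cortex, 6 in sensory cortex and 965 over both regions.

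In 13 of 452 groups examined a sample lay far from the others, where 1 in 20 would be about 22.6. Many of the groups share arrays and genes, so the 13 cannot be judged against that number. For each flagged sample the share of the range taken up by its gap is given. In motor cortex of EAE mice these were Plin4 in mouse 1 (8.78 against 9.39 to 9.60, gap 0.741), Il1r1 in mouse 6 (8.98 against 8.74 to 8.80, gap 0.752) and Arc in mouse 2 (11.19 against 12.16 to 12.62, gap 0.684). In motor cortex of healthy mouse 2 the array median was low (8.24 against 8.28 to 8.29, gap 0.85) and Mbp (14.58 against 14.33 to 14.35, gap 0.922), Aspa (10.46 against 9.99 to 10.02, gap 0.92) and Ighm (12.69 against 12.39 to 12.43, gap 0.852) were high. In the same group the actin 3' minus 5' difference was low in mouse 4 (0.345 against 0.69 to 0.744, gap 0.864), an array of the second processing day, and Pvalb was low in mouse 3 (12.90 against 13.10 to 13.13, gap 0.864). In sensory cortex Ngp was high in EAE mouse 6 (8.99 against 7.75 to 8.02, gap 0.781), Vwf was low in healthy mouse 1 (8.24 against 8.63 to 8.68, gap 0.888), also of the second day, Ciita was low in healthy mouse 3 (7.12 against 7.15 to 7.15, gap 0.931), and healthy mouse 3 had the highest mean correlation with its group (0.997 against 0.996 for the others, gap 0.84).

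Among 10092 probe sets with no single gene symbol, array controls left out, which enter no comparison above, 25 were called in motor cortex (9 higher and 16 lower) and 26 in sensory cortex (19 higher and 7 lower) by limma over all probe sets.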

How the results depend on the processing

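The settings with covariates, with EAE mice alone and with cohort means taken off the grades were chosen after the data were seen. Among 80 genes followed in each region no call changed sign; in motor cortex 1530 values kept their side of the threshold, 241 lost it and 56 gained it, and in sensory cortex 1228, 549 and 50. The cause of each shift below was not tested, except that leaving mice out lowers the number compared. In motor cortex 410 genes became 905 with array weights, 194 without the second array day, and 9 and 16 in cohorts 1 and 2; in sensory cortex 438 became 260 over every probe set, 782 without dim genes, 800 with trend and robust, 2549 with array weights, 118 without the second day, 0 in cohort 1 (limma, 871 at an unadjusted p under 0.05), 141 in cohort 2, 6 with the covariates and 1015 in 1 fit over all arrays. For both regions 1431 became 2568 with array weights, 6 without the second day (both arrays of 2 of the 4 healthy mice), and 0 and 574 in cohorts 1 and 2. For motor against sensory cortex 2408 became 3771 over every probe set, 1531 without the second day, 1338 in healthy mice and 728 in EAE mice. Without each mouse in turn the counts ranged from 145 to 470 (motor), 19 to 1009 (sensory), 472 to 1813 (both) and 1925 to 2912 (between regions). The difference between regions was 0 by limma in every setting run, with 269 to 920 genes, or 1008 probe sets, at an unadjusted p under 0.05.

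By the labels' animal numbers, the EAE and healthy mice that share a number are different animals. Their deviations correlated at 0.0156 to 0.292 in motor and -0.25 to 0.397 in sensory cortex. That overlaps the -0.0316 to 0.587 between the 2 arrays of a mouse, so the correlations alone cannot settle the pairing. With the number as a replicate block, over mice 1 to 4 of each condition, 389 genes were called in motor cortex, 5 in sensory cortex, 919 for both and 0 for the difference between regions. Without the mouse as a block, 1968 genes differed between the regions.

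Of 16 lists called in motor cortex, 3 held with an estimated correlation and 8 passed fry; of 15 in sensory cortex, 0 and 7. Without each mouse in turn 13 to 17 and 14 to 16 lists were called. The number of arrays and signal near background limit what dim genes show.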

Other observations

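Several genes outside the lists were among those with the smallest adjusted p over both regions together, by the same limma fit. The peptide gene Apln, whose receptor acts in vessel growth, fell by 0.73 ± 0.08 (SE, log2), the sialomucin gene Emcn fell by 0.68 ± 0.07, the interleukin-17 receptor gene Il17ra fell by 0.52 ± 0.06 and the glutamine transporter gene Slc38a3 fell by 0.45 ± 0.05. The matrix protein gene Matn2 rose by 0.89 ± 0.07, the cytochrome P450 genes Cyp1b1 and Cyp2d22 by 0.83 ± 0.09 and 0.44 ± 0.05, and the phospholipase gene Pla1a by 0.47 ± 0.05. Matn2, Emcn and Apln were called in each region alone, and there whichever mouse was left out. The organic anion transporter gene Slc22a8 fell by 0.77 ± 0.14 in motor and fell by 0.56 ± 0.11 in sensory cortex, and the retinoid isomerase gene Rpe65 fell by 0.67 ± 0.15 and fell by 0.95 ± 0.16.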
